A study of Mus musculus with 18 samples.

How the data were processed

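ATAC-seq, which uses the Tn5 transposase to cut and tag open chromatin, was carried out on 18 mouse libraries. Per the labels, 9 libraries came from mPTCL, which are murine peripheral T-cell lymphomas that arose after p53-knockout T cells were transferred into CD3-deficient C57BL/6 mice. The sorted lymphoma cells came from the liver, and the labels name no markers for that sort. The 9 other libraries came from wild-type cells in groups of 3. T cells were CD3-positive and Thy1-positive cells of the spleen. NK cells were CD27-negative, CD11b-positive cells of the spleen. NKT cells were liver cells positive for CD3 and for a CD1d tetramer loaded with alpha-galactosylceramide, although their titles carry the abbreviation Sp. Per the labels' protocols, each library was made from 10000 sorted cells and amplified by PCR with Nextera primers. Genotype and sort gate therefore differ together between the lymphomas and each normal group, and tissue differs as well against the T and NK cells of the spleen, so no comparison can separate them. The labels do not say that the 3 normal libraries of a group came from separate animals, so p-values measure the spread between these samples, which could be technical. Lymphomas are numbered 1 to 9 in accession order, and their numbers have no other meaning.

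The deposited tables hold whole-number read counts per peak, not normalized, for all 18 libraries. The authors named MACS2 2.1.2 and edgeR 3.24.3 along with bedtools and the mm10 build, per the submitters' processing notes. The aligner, the duplicate filter, any shift of read ends for the Tn5 offset and the rule that chose the peaks are not given in the sources used here. A table of 61224 peaks of 500 bp was the main table, and a table of 27727 peaks was analysed in the same way as an alternative. The 2 tables share 14905 intervals with the same chromosome and start. Both hold the 19 autosomes and no sex chromosome. Because the rule that chose the peaks is unknown, a share of called peaks is a share of that set only. Positions are printed as deposited, and whether they count from 0 or from 1 is not stated. The authors also deposited log2 CPM values per peak, whose effective library sizes equal those of TMM scaling recomputed from the counts. Each peak carries a deposited class (promoter, 5' UTR, exonic, intronic, 3' UTR, flanking or intergenic) and a gene symbol. Of 19234 intronic gene assignments with a symbol in RefSeq GRCm38.p6, 93.9% lay within that gene. No library column was left unmapped.

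Total counts in peaks set the depth. They ran from 670358 to 4844441 in the lymphomas, 979441 to 2358023 in T, 1433904 to 9097014 in NKT and 417107 to 596601 in NK cells. Between 0.0343% and 24.7% of peaks had no count in a library. Counting intervals and floors cover counting error only, since PCR reads without molecular identifiers are not independent molecules. A group with 0 counts in all its libraries was given a floor of 3 counts over the group, and a ratio against 1 to 3 counts has an exact binomial interval at 95% confidence. The closest pair of libraries within a group still differed by 2.295 in chi-square per degree of freedom, so no pair was counted as 1 library.

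Counts were tested with edgeR 4.0.16 in R 4.3.3 (limma 3.58.1; the data.table package at version 1.17.8). TMM scaling, filterByExpr by group and 1 quasi-likelihood fit over all 18 libraries and 4 groups (glmQLFit and glmQLFTest) were used for 6 comparisons. Adjusted p-values are Benjamini-Hochberg values over all features of a comparison, with a threshold of 0.05. The filter kept 61220 peaks, and the biological coefficient of variation was 0.431 with 14 residual degrees of freedom. Gene values are counts summed over all peaks the deposited annotation gives a symbol, for 20326 genes, with a coefficient of 0.297. A peak given 2 symbols counts toward both. Fold changes are log2 with their standard error (SE), and log2 CPM uses a prior count of 2. All p-values are two-sided. The NK-over-T signature took peaks that differed between the 3 NK and 3 T libraries alone at an adjusted p below 0.05 and a log2 fold change of at least 1. It is the mean log2 CPM of NK-higher peaks minus that of T-higher peaks, compared between lymphomas and NKT cells by an exact permutation test. Similarity is Spearman's rho across peaks with each normal group's mean, and peaks are not independent replicates. Location was tested with Fisher's exact test on the deposited classes.

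A total of 16 gene lists, the genes always named, the tests and most alternatives were fixed before the data were examined. The lists were NK receptors, NK receptor signalling, cytotoxic effectors, TCR complex and signalling, T-cell transcription factors, NK and effector transcription factors, NKT-cell genes, chronic stimulation and exhaustion, p53 targets, cell cycle and growth, homing and tissue residency, and markers of B cells, myeloid and Kupffer cells, hepatocytes, endothelial and stromal cells, and erythroid cells. Lists were tested with camera at its preset correlation of 0.01, with an estimated correlation, and with fry, adjusted over the 16 lists of a comparison. Camera compares a list with all other genes, whereas fry asks whether the list itself moved one way. Named peaks were the 5 higher and 5 lower peaks with the largest fold change among those past the threshold, changed at least 2-fold, above the median level and without overlap between the libraries of both groups. Only 1 peak was taken per gene. Predicted genes, Klra genes and receptor segments were left out of that choice. Named genes were the up to 4 members of each list with the smallest p in a comparison, plus a fixed set of T-cell, NK-cell and growth genes. Some genes and peaks that these rules choose are not reported here, in the text or the figures.

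The fits were tested on simulated counts with 200 changed features. At the peak level, 55.3% of 4-fold and 5.3% of 2-fold changes were recovered for mPTCL against NKT, 52.1% and 3.2% against T, and 29.8% and 3.2% against NK (58667 peaks). At the gene level, 81.2% of 4-fold and 35.1% of 2-fold changes were recovered against NKT, 82.3% and 35.1% against T, and 80.2% and 29.9% against NK (19815 genes). Peak-level false calls numbered 2 against NKT, 3 against T and 0 against NK. Gene-level false calls numbered 1, 10 and 3 in the same order. The simulation gave a feature the same dispersion in all groups and changed only 200 features. It therefore does not cover the unequal spread of the real groups or changes at many features.

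Alternatives were DESeq2 size factors (RLE), library totals, the deposited library sizes, cyclic-loess values with limma-trend, other filters, DESeq2 1.42.0, a fit on the 2 groups alone, voom with a variance weight per group, a 2-fold threshold, the other table, a replicate block and leaving out each library. Those added after the data were seen were TMM within each chromosome, promoter peaks only, leaving out the 3 NK libraries, the 9 normal libraries alone, and several of the above applied to gene lists, named genes, the signature and similarity. Where a list was compared with random lists, 10000 lists were drawn from genes within 100 ranks in mean log2 CPM. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.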

Results

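Chromatin accessibility was measured by ATAC-seq in 9 murine peripheral T-cell lymphomas (mPTCL) and in 3 libraries of each of 3 normal lymphocytes (T, NKT and NK). NK cells are innate lymphocytes that kill without a T-cell receptor, and NKT cells are T cells that carry an invariant receptor for lipids on CD1d together with several NK-cell receptors. The lymphomas arose from T cells that lacked p53, so the design asks how their open chromatin differs from that of each normal lymphocyte. The count table held 61224 peaks of 500 bp on the mm10 build. By the deposited annotation, 32.6% of the peaks lay at promoters, 31.7% in introns, 15.7% between genes and 9.31% in regions flanking genes. A further 6.58% were exonic, 3.07% lay in 3' UTRs and 0.991% in 5' UTRs.

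Total counts in peaks were 2044776 in mPTCL 1, 1422130 in mPTCL 2, 3771074 in mPTCL 3, 2348268 in mPTCL 4, 3327815 in mPTCL 5, 4325708 in mPTCL 6, 4844441 in mPTCL 7, 670358 in mPTCL 8 and 1040523 in mPTCL 9. The T libraries 1 to 3 held 979441, 1245437 and 2358023 counts, and the NKT libraries 1433904, 8268896 and 9097014. The NK libraries were the shallowest, with 428211, 417107 and 596601 counts and a median of 4, 4 and 6 counts per peak. The correlation of log2 CPM across peaks between libraries of a group had a median of 0.636 over 36 pairs of lymphomas (0.542 to 0.788). That median was 0.839 in T, 0.908 in NKT and 0.501 in NK cells, over 3 pairs each. Across peaks, the SD within a group had a median of 0.66 log2 units in the lymphomas, 0.50 in T, 0.37 in NKT and 1.07 in NK cells. In the 84 subsets of 3 lymphomas this median averaged 0.56 and ranged from 0.40 to 0.68.

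Trp53, the gene of the p53 tumour suppressor, is the gene the labels name as knocked out, and 3 peaks on chromosome 11 were annotated to it. At the promoter peak at 69578979 to 69579479, the lymphomas 1 to 9 had 43.0, 25.0, 69.0, 47.1, 34.6, 58.4, 31.9, 49.6 and 41.0 CPM. The T libraries had 42.3, 31.1 and 37.7 CPM, the NKT libraries 22.4, 34.0 and 31.8 CPM, and the NK libraries 29.8, 11.3 and 7.13 CPM. A second promoter peak at 69580212 to 69580712 ranged from 18.6 to 47.7 CPM in the lymphomas, and in the 9 normal libraries from 0 counts in NK 2 to 43.8 CPM. The exonic peak at 69589205 to 69589705 ranged from 3.17 to 15.8 CPM in the lymphomas, and in the normal libraries from 0 counts in T 2 and NK 3 to 13.4 CPM. All these CPM include a prior count. The labels do not say which part of the gene was deleted, and open chromatin can remain at a disabled gene, so these peaks do not check the labels. Summed over its peaks, Trp53 was 0.96 ± 0.25 log2 units (SE) higher in mPTCL than in NKT cells (adjusted p = 0.00374, edgeR), a call that was lost with TMM within each chromosome (0.48). It lies on chromosome 11, whose share of counts was raised in the lymphomas.

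Against NKT cells, the lymphomas (n = 9 against 3) were less accessible at Cd4, the co-receptor of helper T cells, by the widest margin of any preset gene. In the gene-level fit, its 1 peak lay -5.17 ± 0.35 log2 units from NKT cells (adjusted p = 2.7e-10, edgeR). The peak-level fit, a separate fit, gave -5.46 ± 0.34. Slamf6, a receptor needed for NKT-cell development, differed by -2.11 ± 0.33, and the costimulatory receptors Icos and Cd28 by -2.34 ± 0.34 and -2.08 ± 0.33. Higher in the lymphomas were Ncr1, which encodes the activating NK receptor NKp46, at 4.5 ± 0.78, Eomes, a transcription factor of NK and memory T cells, at 2.98 ± 0.41, and Plcg2, a phospholipase of B-cell and NK-cell receptor signalling, at 2.31 ± 0.25. Fold changes here and for the other comparisons are log2 values with their SE.

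Over all 20326 genes, 5175 were higher and 4096 lower in the lymphomas than in NKT cells, which is 45.6% called (edgeR). A list with a similar share of calls does not stand out by its counts. Among the 28 TCR complex and signalling genes, 15 were lower and 2 higher in the lymphomas than in NKT cells, and 11 were not called. Adjusted over the list alone, 17 were lower and 2 higher. Cd6, a coreceptor of T cells, differed by -1.43 ± 0.24. The list median was -0.77 (camera, adjusted p = 0.00582, but adjusted p = 0.174 with an estimated correlation). Of 18 T-cell transcription factors, 7 were lower, 0 higher and 11 not called, also when adjusted over the list alone. Ets1 differed by -1.29 ± 0.18 and Bach2, a repressor that keeps T cells naive, by -0.72 ± 0.16, whereas Bcl11b (-0.16 ± 0.20), Tcf7 (-0.05 ± 0.24) and Lef1 (-0.26 ± 0.22) were not called. That list had a median of -0.24 (camera, adjusted p = 0.0291, and adjusted p = 0.174 with an estimated correlation). Of 17 measured NKT-cell genes, 7 were lower, 1 was higher and 9 were not called, with the same counts adjusted over the list alone and a median of -0.61. Rora differed by -1.05 ± 0.17 and Egr2, which acts early in NKT development, by -0.78 ± 0.17. Zbtb16, which encodes the NKT-lineage factor PLZF, differed by -2.27 ± 0.37 but was not called in the other table (-1.13). The list was lower by camera (adjusted p = 0.00582, but adjusted p = 0.0527 with an estimated correlation).

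Most of the 15 NK receptor signalling genes differed the other way, with 10 higher, 1 lower and 4 not called against NKT cells. Counts were the same adjusted over the list alone, and the median was 1.16. Lat2, an adaptor of B and NK cells, was 2.81 ± 0.39 higher and the kinase Lyn 1.55 ± 0.31 higher. The list was higher by camera (adjusted p = 0.00633, but adjusted p = 0.0527 with an estimated correlation). Of 20 measured NK receptors (32 were listed), 7 were higher, 3 lower and 10 not called, with the same counts adjusted over the list alone. Cd244a, which encodes the receptor 2B4, was 1.35 ± 0.25 higher, and Klrk1, which encodes NKG2D, was not called (-0.17 ± 0.26). The median of the receptors was 0.56, and the list was not called by camera (adjusted p = 0.15) although fry called it higher (adjusted p = 0.0369). Of 16 cytotoxic effectors, 6 were higher, 4 lower and 6 not called, also adjusted over the list alone (median 0.03, camera, adjusted p = 0.375). Within it the chemokine genes Ccl3 and Ccl4 were 3.01 ± 0.47 and 1.99 ± 0.28 higher and the granzyme gene Gzma 2.33 ± 0.37 higher. Ifng, the gene of interferon gamma, differed by -1.12 ± 0.23, and Gzmb (-0.09 ± 0.30) and Prf1 (-0.47 ± 0.21) were not called. Of 15 NK and effector transcription factors, 3 were higher and 4 lower, with 6 lower adjusted over the list alone (median 0.20, camera, adjusted p = 0.948). Under RLE they were 3 and 1, and under library totals 3 and 2. Smad3 differed by -0.81 ± 0.19, and Tbx21, the gene of T-bet, was not called (0.28 ± 0.19).

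Of 31 cell cycle and growth genes, 6 were higher and 6 lower than in NKT cells, the same adjusted over the list alone, with a median of 0.03 (camera, adjusted p = 0.905). Under RLE they were 7 and 2, and under library totals 7 and 3. Cdkn2a, which encodes the tumour suppressors p16 and p19Arf, was 1.77 ± 0.25 higher, Ccnd1, which encodes cyclin D1, 1.94 ± 0.30 higher and Mycn 2.60 ± 0.42 higher. The cell-cycle inhibitor gene Cdkn1b differed by -0.89 ± 0.17. Myc was 1.27 ± 0.22 higher, lay on chromosome 15, whose share of counts was raised, and was not called with TMM within each chromosome (0.41). With that scaling, 18 of 136 named genes lost their call against NKT cells, 9 gained one and 3 changed sign. Of 21 measured p53 targets, 5 were lower and 1 higher, also adjusted over the list alone (median -0.32, camera, adjusted p = 0.0859), and fry called this list lower (adjusted p = 0.00173). Cdkn1a, the p53 target that encodes p21, was not called (0.30 ± 0.34). Of 21 genes of chronic stimulation and exhaustion, 3 were higher and 4 lower, or 3 and 3 adjusted over the list alone, but 5 and 2 under RLE and 4 and 2 under library totals. Nr4a2 was 2.21 ± 0.29 and Rgs16 1.90 ± 0.48 higher, while Pdcd1, which encodes PD-1, was not called (-0.45 ± 0.21). The list's median was -0.26 and camera pointed down (adjusted p = 0.494), although its mean was 0.04. Of 16 homing and residency genes, 5 were higher and 2 lower, also adjusted over the list alone (median 0.36, camera, adjusted p = 0.576), with Itga4, an integrin subunit, 1.47 ± 0.39 higher.

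Beside the groups above, some markers of other cell types were also more accessible in the lymphomas than in NKT cells. Of 7 B-cell markers, 5 were higher and 0 lower (6 higher adjusted over the list alone, median 1.54), with Pax5 at 2.21 ± 0.39. The list was called by camera (adjusted p = 0.0194, but adjusted p = 0.0527 with an estimated correlation). Of 8 endothelial and stromal markers, 5 were higher, also adjusted over the list alone (median 1.85), with Stab2 at 3.08 ± 0.61 and Col1a1 at 1.81 ± 0.26. This list was called as well (camera, adjusted p = 0.0195, but adjusted p = 0.0527 with an estimated correlation). Of 6 hepatocyte markers, 5 were higher, also adjusted over the list alone (median 1.58), with G6pc at 2.84 ± 0.49 (camera, adjusted p = 0.0404, but adjusted p = 0.181 with an estimated correlation). Of 10 myeloid and Kupffer-cell markers, 6 were higher and 1 lower, also adjusted over the list alone (median 1.43, camera, adjusted p = 0.0781), with Cd68 at 2.81 ± 0.49. Of 5 erythroid markers, 2 were higher, or 3 adjusted over the list alone (median 0.99, camera, adjusted p = 0.125). Fry called the myeloid and erythroid lists higher (adjusted p = 0.000253 and 0.000677). Under RLE or library totals, the median gene lay 0.19 or 0.17 above NKT cells in place of 0.06 under TMM, and no list called by camera changed the sign of its median.

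Over all peaks, 14225 were higher and 11871 lower in the lymphomas than in NKT cells, which is 42.6% of the 61220 tested (edgeR, adjusted p below 0.05). Under TMM, the median fold change ran from 2.47 in the weakest to -0.75 in the strongest of 10 equal classes of mean level. The median over all peaks was 0.27 under TMM, 0.74 under RLE and -0.02 on cyclic-loess values, so how far any class moved depends on the scaling. The largest gains included a 3' UTR peak of Nfkb1 on chromosome 3 at 135585291 to 135585791 (5.87 ± 0.77), a gene that encodes a subunit of NF-kappaB. Other large gains were an exonic peak of Tmtc1 on chromosome 6 at 148294634 to 148295134 (6.42 ± 0.82) and a promoter peak of A2ml1 on chromosome 6 at 128543396 to 128543896 (5.73 ± 0.76). The Nfkb1, Tmtc1 and A2ml1 peaks had only 8, 4 and 5 counts over the 3 NKT libraries. NK cells averaged 5.96, 5.34 and 1.59 log2 CPM at them, against 4.61, 4.56 and 4.31 in the lymphomas. Intronic peaks of Dagla on chromosome 19 at 10279703 to 10280203 and of Zdhhc14 on chromosome 17 at 5567824 to 5568324 had 1 and 3 counts over the 3 NKT libraries. Their CPM ratios were 227 (95% counting interval 40.5 to 8992) and 83.7 (28.4 to 407.5). The largest losses were an intronic peak of Cd4 on chromosome 6 at 124884987 to 124885487 (-5.46 ± 0.34) and an intronic peak of Rin2 on chromosome 2 at 145832394 to 145832894 (-5.43 ± 0.38). Next came exonic peaks of Arpc2 on chromosome 1 at 74262558 to 74263058 (-4.88 ± 0.44) and of Dpp4 on chromosome 2 at 62352004 to 62352504 (-4.81 ± 0.56), and an intronic peak of Cblb on chromosome 16 at 52147385 to 52147885 (-4.76 ± 0.40). Dpp4 encodes the T-cell surface protease CD26 and Cblb a ubiquitin ligase that restrains T-cell activation. Higher peaks made up 54.5% of the calls under TMM but 79.2% under RLE, 74.6% under library totals, 80.3% with DESeq2 and 42.7% on cyclic-loess values. The total of 26096 calls fell to 7567 on cyclic-loess values, 12052 among peaks with a mean count of at least 20 and 7008 in the other table, and to 14458 without NKT 2 and 16747 without NKT 3.

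Against T cells, the lymphomas (n = 9 against 3) were more accessible at several genes of cytotoxic lymphocytes. Ccl5, a chemokine gene of effector T and NK cells, was 2.51 ± 0.28 higher, Gzmb, which encodes granzyme B, 2.37 ± 0.40 higher, and Ifng 2.25 ± 0.32 higher. Tbx21, the gene of the effector factor T-bet, was 1.91 ± 0.22 higher (adjusted p = 1.6e-06, edgeR), and Klrg1, an inhibitory receptor of mature NK and effector T cells, 2.55 ± 0.37 higher. Tbx21 lies on chromosome 11, whose share of counts was raised in the lymphomas. With TMM within each chromosome, 15 of 136 named genes lost their call against T cells, 15 gained one and 3 changed sign. Cd4 differed by -2.08 ± 0.41, Cd5, a negative regulator of the T-cell receptor, by -1.94 ± 0.42, and Tox, a factor of T-cell development and exhaustion, by -1.42 ± 0.20.

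Over all 20326 genes, 3296 were higher and 2984 lower than in T cells, which is 30.9% called and the base for the list counts here. Of the 16 cytotoxic effectors, 10 were higher than in T cells, 1 was lower and 5 were not called, also adjusted over the list alone. Gzma was 2.13 ± 0.39 and Nkg7, a granule protein gene, 1.18 ± 0.30 higher, and Prf1, which encodes perforin, was not called (-0.13 ± 0.23). The list median was 1.35 (camera, adjusted p = 6.6e-05, but adjusted p = 0.0971 with an estimated correlation). Of 20 NK receptors, 11 were higher, 0 lower and 9 not called, with 13 higher adjusted over the list alone and a median of 1.0. Slamf7 was 1.40 ± 0.21 higher but was not called from promoter peaks alone, and Klrk1 was not called (0.20 ± 0.28). The receptors as a list were higher by camera (adjusted p = 0.00103, but adjusted p = 0.128 with an estimated correlation). Of 15 NK receptor signalling genes, 6 were higher, 0 lower and 9 not called, with 8 higher adjusted over the list alone and a median of 0.97. Tyrobp, which encodes the adaptor DAP12 of activating NK receptors, was 2.08 ± 0.35 higher and Sh2d1b1, an NK-cell adaptor gene, 3.18 ± 0.86 higher. This list was also higher (camera, adjusted p = 0.00103, but adjusted p = 0.0725 with an estimated correlation). Of 15 NK and effector transcription factors, 4 were higher and 0 lower, also adjusted over the list alone (median 0.65, camera, adjusted p = 0.054), and fry called this list higher (adjusted p = 2.3e-05). Runx3 was 0.94 ± 0.21 higher, and Eomes was not called (0.78 ± 0.35).

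Of the 28 TCR complex and signalling genes, 10 were lower than in T cells, 3 were higher and 15 were not called, also adjusted over the list alone (median -0.40, camera, adjusted p = 0.0565). Icos differed by -1.49 ± 0.37, and Cd3e (-0.23 ± 0.29) and Lck (-0.12 ± 0.22) were not called. Of 18 T-cell transcription factors, 2 were higher and 2 lower, also adjusted over the list alone, with a median of -0.01 but a mean of 0.01 (camera, adjusted p = 0.68). Bcl11b (0.14 ± 0.20) and Tcf7 (-0.22 ± 0.24) were not called. Of 17 NKT-cell genes, 7 were higher and 3 lower, also adjusted over the list alone (median 0.42, camera, adjusted p = 0.308), and fry called this list higher (adjusted p = 0.0128). The cytokine gene Il4 was 2.04 ± 0.36 higher and Slamf6 differed by -1.85 ± 0.35, and Zbtb16 was not called (-0.30 ± 0.45).

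Of 21 p53 targets, 7 were lower than in T cells and 1 higher, or 8 and 2 adjusted over the list alone (median -0.50, camera, adjusted p = 0.0565), and fry called this list lower (adjusted p = 0.00131). Of 21 chronic stimulation and exhaustion genes, 5 were higher and 4 lower, or 6 and 4 adjusted over the list alone. Cd38 was 2.16 ± 0.38 higher and Cd200 differed by -2.40 ± 0.41. That list had a median of -0.06, a mean of 0.07 and a camera test pointing down (adjusted p = 0.91). Of 31 cell cycle and growth genes, 5 were higher and 5 lower, also adjusted over the list alone. Cdkn2a was 2.56 ± 0.29 higher and the replication factor gene Mcm3 differed by -1.15 ± 0.20. The list had a median of -0.02, a mean of 0.08 and a camera test pointing down (adjusted p = 0.833). Of 16 homing and residency genes, 7 were higher and 2 lower, also adjusted over the list alone (median 0.15, camera, adjusted p = 0.337). Itgae, which encodes the residency integrin CD103, was 1.76 ± 0.27 higher. Beside these groups, 4 of 7 B-cell markers were higher than in T cells (5 adjusted over the list alone, median 0.93, camera, adjusted p = 0.0565). The same held for 4 of 10 myeloid and Kupffer-cell markers (median 0.97, adjusted p = 0.11), 3 of 6 hepatocyte markers (0.77, adjusted p = 0.0565), 3 of 8 endothelial and stromal markers (1.08, adjusted p = 0.0823) and 0 of 5 erythroid markers (0.51, adjusted p = 0.595; 0 also at an unadjusted p below 0.05). These 4 counts were the same adjusted over the list alone, and no marker was lower. Fry called the B-cell, myeloid, hepatocyte and endothelial lists higher (adjusted p from 4.13e-05 to 0.00287).

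Over all peaks, 5061 were higher and 6999 lower in the lymphomas than in T cells, which is 19.7% of those tested (edgeR). Peaks in introns of Rasgef1a on chromosome 6 at 118018527 to 118019027 and of Slc35f3 on chromosome 8 at 126257955 to 126258455 had 0 counts in all T libraries. So did a promoter peak of Col22a1 on chromosome 15 at 72034009 to 72034509. They were at least 25.8-fold, 24.9-fold and 25.8-fold higher in the lymphomas, against a floor of 3 counts over the T group. An intronic peak of Tdp1 on chromosome 12 at 99942439 to 99942939 had 3 counts over the T libraries and a CPM ratio of 41.6 (14.2 to 202.3), and an intronic peak of Tbc1d16 on chromosome 11 at 119159494 to 119159994 was 4.91 ± 0.59 higher. The largest loss lay at a promoter peak shared by Tle1, which encodes a Groucho-family corepressor, and C630043F03Rik on chromosome 4 at 72200768 to 72201268 (-6.16 ± 0.28). Other large losses were a promoter peak of the DNA repair gene Mgmt on chromosome 7 at 136894342 to 136894842 (-4.75 ± 0.47) and intronic peaks of Trmt11 on chromosome 10 at 30538261 to 30538761 (-4.62 ± 0.46) and of Eipr1 on chromosome 12 at 28834339 to 28834839 (-4.61 ± 0.45). A 5' UTR peak of Cyp2r1, which encodes a vitamin D hydroxylase, on chromosome 7 at 114562248 to 114562748 differed by -4.58 ± 0.37. Higher peaks made up 42.0% of calls under TMM but 63.5% under RLE, 57.7% under library totals and 69.8% with DESeq2. The total of 12060 became 18306 with DESeq2, 18396 with voom, 7649 on cyclic-loess values and 4797 in the other table, and 6048, 6265 and 7382 without T 1, T 2 and T 3.

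Against NK cells, the lymphomas (n = 9 against 3) were more accessible at Cd3e, a chain of the T-cell receptor complex, by 2.55 ± 0.50 (adjusted p = 0.00077, edgeR). Bcl11b, a factor that commits cells to the T lineage, was 1.02 ± 0.23 higher, and the cytokine gene Il4 1.97 ± 0.43 higher. Syk, a kinase of NK and B cells, differed by -1.90 ± 0.40, and Bhlhe40, a factor of activated lymphocytes, by -1.5 ± 0.24. None of the 20 NK receptors was called in either direction by edgeR, with 2 higher at an unadjusted p below 0.05. Examples are Ncr1 (-0.83 ± 0.58), Klrd1 (0.22 ± 0.31) and Klrb1c, which encodes NK1.1 (-0.66 ± 0.42).

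No list was called against NK cells by camera, with adjusted p-values from 0.755 to 0.982, and none with an estimated correlation, nor was any below 0.05 before adjustment. Over all 20326 genes, 2279 were higher and 2086 lower than in NK cells, which is 21.5% called and the base for the list counts here. Of 28 TCR complex and signalling genes, 7 were higher and 3 lower, or 11 and 4 adjusted over the list alone (median 0.38). Of 15 NK receptor signalling genes, 2 were higher and 4 lower, or 3 and 4 adjusted over the list alone (median -0.13). Sh2b3, an adaptor that restrains cytokine signalling, was 1.26 ± 0.21 higher. The NK receptors had 0 calls also adjusted over the list alone (median 0.27). Of 16 cytotoxic effectors, 2 were higher and 1 lower, also adjusted over the list alone (median 0.19), and Gzma (0.18 ± 0.36) and Gzmb (0.17 ± 0.36) were not called. Of 15 NK and effector transcription factors, 2 were higher and 2 lower, also adjusted over the list alone. Tbx21 was 1.2 ± 0.23 higher and Eomes was not called (0.87 ± 0.41), and this list had a median of 0.18 while camera pointed down. Of 18 T-cell transcription factors, 2 were higher and 3 lower, also adjusted over the list alone (median -0.09). Of 17 NKT-cell genes, 2 were higher and 3 lower, or 6 and 3 adjusted over the list alone (median 0.50). Of 31 cell cycle and growth genes, 8 were higher and 3 lower, also adjusted over the list alone (median 0.13), and fry called this list higher (adjusted p = 0.00775). The mitotic genes Top2a and Aurkb were 1.84 ± 0.33 and 1.5 ± 0.27 higher, and Cdkn2a was 1.55 ± 0.29 higher. Il4, Tbx21, Top2a and Aurkb lie on chromosome 11 and Sh2b3 on chromosome 5, whose shares of counts were raised. With TMM within each chromosome they were 1.40, 0.65, 1.27, 0.94 and 0.76 higher and kept their calls, while 19 of 136 named genes lost theirs against NK cells.

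Of 21 chronic stimulation genes, 1 was higher and 2 lower than in NK cells, and of 21 p53 targets 1 was higher and 3 lower (medians -0.0005 and -0.16). Of 16 homing genes, 3 were higher and 3 lower (median 0.27). None of the B-cell, myeloid, hepatocyte or erythroid markers was called against NK cells by edgeR, and 0, 1, 1 and 0 were higher at an unadjusted p below 0.05. Their list medians were 0.29, 0.49, 0.30 and 0.44. Of 8 endothelial and stromal markers, 1 was higher and 1 lower, with a median of 0.04 and a mean of -0.01. All counts of the preceding sentences were the same adjusted over the list alone. At an adjusted p below 0.05, the test had found 80.2% of simulated 4-fold but 29.9% of simulated 2-fold gene changes against NK cells, so a member that was not called could still differ 2-fold.

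Over all peaks, 3694 were higher and 2302 lower in the lymphomas than in NK cells, which is 9.79% of those tested (edgeR). The 5 higher peaks chosen had 0 counts in all NK libraries. An intronic peak of Col22a1 on chromosome 15 at 71917706 to 71918206 was at least 12.4-fold higher, and a flanking peak of Dok7 on chromosome 5 at 35054443 to 35054943 at least 13.9-fold higher, against 3 counts over the NK group. On the same floor, an intronic peak of Celsr1 on chromosome 15 at 86027736 to 86028236 was at least 10.65-fold higher. A promoter peak of Klhl32 on chromosome 4 at 24850726 to 24851226 was at least 10.8-fold higher, and an exonic peak of Baiap2l2 on chromosome 15 at 79270894 to 79271394 at least 11.6-fold higher. The largest losses included an intronic peak of Plxdc2 on chromosome 2 at 16682729 to 16683229 (-6.34 ± 0.51) and an exonic peak of Cdc27, a subunit of the anaphase-promoting complex, on chromosome 11 at 104528170 to 104528670 (-5.52 ± 0.48). The Tle1 promoter peak differed by -5.40 ± 0.29, and a promoter peak of Phxr2 on chromosome 10 at 99127024 to 99127524 by -4.97 ± 0.44. Higher peaks made up 61.6% of the calls under TMM and 24.6% with voom. The total of 5996 became 11269 on cyclic-loess values and 1832 with voom, and 3394 and 3769 without NK 2 and NK 3.

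**Figure D1:**
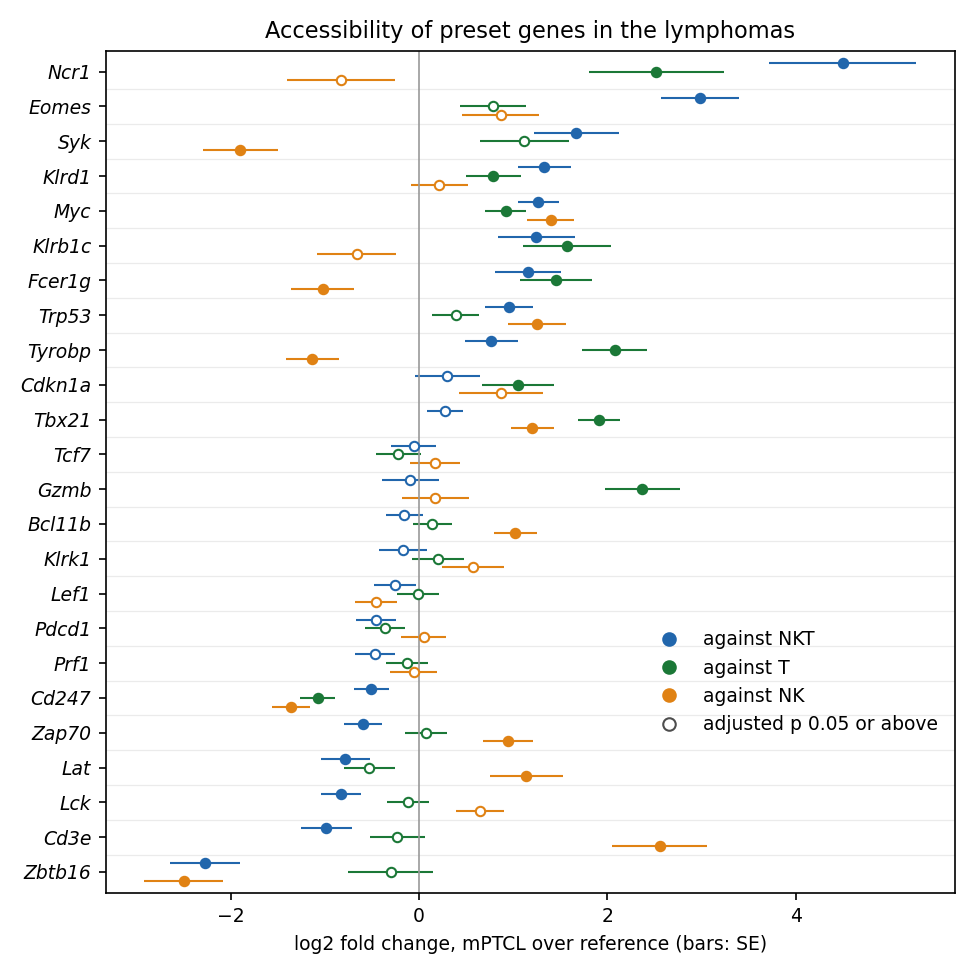
Log2 fold change of genes fixed in advance, lymphomas over NKT (blue), T (green) and NK cells (orange), with bars for the SE and open circles where the adjusted p was 0.05 or above (n = 9 against 3). Ncr1 lay 4.5 above NKT cells and Zbtb16 2.27 below them on the log2 scale (-2.27), and Cd3e lay 2.55 above NK cells.

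The NK-over-T signature asked where the lymphomas lay between NK and T cells, using 1272 peaks higher in NK and 532 peaks higher in T cells. The signature was 0.30 ± 0.26 log2 units (SD, n = 9) in the lymphomas and -0.84 ± 0.10 (SD, n = 3) in NKT cells. T cells at -2.44 ± 0.22 and NK cells at 2.73 ± 0.61 define its ends, so their values are not tests. All 9 lymphomas lay above all 3 NKT libraries, a mean difference of 1.15 (exact permutation test, p = 0.00455, the smallest that 220 splits can give). Peaks higher in T cells had a mean log2 CPM of 3.52 ± 0.24 in the lymphomas and 4.42 ± 0.23 in NKT cells, and 0 of 9 lymphomas lay above the NKT libraries (exact permutation test, p = 0.00455). Peaks higher in NK cells had 3.82 ± 0.15 against 3.57 ± 0.17, with 6 of 9 lymphomas above all NKT libraries (exact permutation test, p = 0.0318). In the other table both parts moved about as far, by -0.46 for peaks higher in T cells (exact permutation test, p = 0.0227) and 0.44 for peaks higher in NK cells (exact permutation test, p = 0.00455). Neither set of peaks was matched on mean level. Against NKT cells, the median fold change ran from 2.47 in the weakest to -0.75 in the strongest of 10 level classes. For NK against T cells, the weakest class held 84 higher and 18 lower peaks, and the strongest 69 and 446. A trend with level was therefore not separated from an NK-like shift. The signature was also not run on cyclic-loess values.

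**Figure D2:**
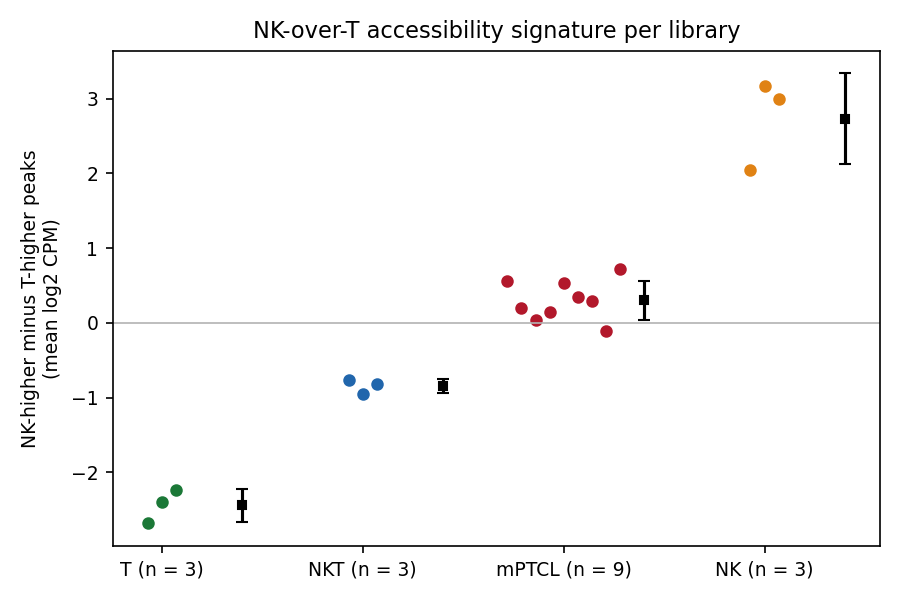
NK-over-T signature (mean log2 CPM of NK-higher minus T-higher peaks) in each library, with squares and bars for the group mean and SD. The lymphomas lay between the NKT mean of -0.84 and the NK mean of 2.73.

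Across all peaks, each lymphoma's log2 CPM was correlated with the mean of each normal group. Spearman's rho averaged 0.603 ± 0.0609 (SD, n = 9) with NKT, 0.551 ± 0.0479 with T and 0.516 ± 0.0316 with NK cells. The NK mean correlated at only 0.547 with its own 3 libraries, against 0.943 for NKT and 0.860 for T cells. Whether the depth of the NK libraries or a spread between the NK samples lowers the values with NK cells was not tested. In the other table the lymphomas averaged 0.719 with NKT, 0.661 with T and 0.660 with NK cells. The first 3 principal components held 24.4%, 16.0% and 10.2% of the variance.

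Among the normal cells, NK differed from NKT cells at 10496 peaks (4168 higher, 6328 lower), NK from T cells at 2936 (1238 and 1698) and NKT from T cells at 3202 (2130 and 1072). Over all 20326 genes, 1730 were higher and 1276 lower in NK than in NKT cells, which is 14.8% called. As a check of the lists, NK signalling genes were higher in NK than in NKT cells (7 of 15 higher and 0 lower, or 8 and 2 adjusted over the list alone, median 1.82). That held by camera (adjusted p = 0.00093) and with an estimated correlation (adjusted p = 0.04). The NKT-cell genes were lower, with 6 of 17 called, also adjusted over the list alone (median -0.67, camera, adjusted p = 0.000624, and adjusted p = 0.0348 with an estimated correlation). The TCR genes were lower too, with 13 lower and 3 higher of 28, or 16 and 3 adjusted over the list alone (median -0.90, camera, adjusted p = 4.06e-05, but adjusted p = 0.108 with an estimated correlation). Other NK-cell lists separated NK from NKT cells less clearly. NK receptors had 6 higher and 1 lower of 20 (median 0.22), and cytotoxic effectors 2 and 2 of 16 (0.14). NK and effector transcription factors had 1 higher and 2 lower of 15 (0.03). Among random lists matched on mean level, these medians lay at percentiles 84.0, 95.6 and 77.6. B-cell markers were higher in NK than in NKT cells as well, with 3 of 7 called, or 4 adjusted over the list alone (camera, adjusted p = 0.0192, but adjusted p = 0.0616 with an estimated correlation), as were endothelial and stromal markers, with 2 of 8, or 4 adjusted over the list alone (camera, adjusted p = 0.0278, but adjusted p = 0.0671 with an estimated correlation). Higher peaks were 39.7% of the NK against NKT calls under TMM, but 76.2% under RLE, 71.7% under library totals and 79.1% with DESeq2. For NK against T these shares were 42.2%, 71.7%, 67.6% and 73.8%, and for NKT against T 66.5%, 50.4%, 52.7% and 40.6%. These totals moved by over 1.5 times under several settings and with 1 library left out, to 4622 to 9560, 1172 to 4097 and 1294 to 1831 in the same order.

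Lower peaks lay at promoters more often than the other peaks tested, and peaks higher than in NKT or T cells less often. Against NKT cells, the odds ratio for a promoter was 0.353 (95% CI 0.337 to 0.370) for higher and 2.64 (2.54 to 2.76) for lower peaks, by Fisher's exact test. Against T cells it was 0.462 (0.430 to 0.497) and 2.43 (2.31 to 2.56). Against NK cells it was 1.27 (1.19 to 1.36) and 2.37 (2.18 to 2.58). Chromosomes 5, 11 and 15, whose shares of counts were raised, held 26.6% of the peaks tested but 45.0%, 43.9% and 54.7% of those higher than in NKT, T and NK cells. Without them, the ratio for higher peaks was 0.356 (0.334 to 0.379), 0.407 (0.368 to 0.449) and 1.06 (0.952 to 1.17), an alternative chosen after seeing the data. Among changes of at least 2-fold, the ratio for lower peaks was 1.36 against NKT, 1.38 against T and 1.54 against NK cells. These intervals treat peaks as independent, which they are not. The ratios rest on TMM calls and were neither matched on peak level nor run under another scaling. Against NKT cells, the weakest of 10 equal classes of mean level held 3425 higher and 9 lower peaks. The strongest class held 39 higher and 3838 lower peaks, so an effect of promoters was not separated from one of level.

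The share of counts on each chromosome was examined after the data had been seen. Chromosomes 5, 11 and 15 held a larger share in all 9 lymphomas than in any of the 9 normal libraries, by a mean of 0.45 ± 0.24, 0.45 ± 0.16 and 0.72 ± 0.22 log2 units (SD, n = 9). Chromosomes 2, 10, 13 and 16 held a smaller share in all 9, by -0.28 ± 0.12, -0.42 ± 0.12, -0.57 ± 0.26 and -0.54 ± 0.23. Each of these 7 had a permutation p of 4.11e-05, the smallest that the 48620 splits can give, and an adjusted p of 0.000112 over 19 chromosomes. A further 7 passed an adjusted p of 0.05, with chromosome 17 raised by 0.26 ± 0.20 and chromosomes 1, 6, 7, 9, 18 and 19 lowered, with means of -0.22 to -0.38. Chromosome 19 passed only over all peaks of the main table (permutation test, adjusted p = 0.0451). It did not pass at promoter peaks of that table (permutation test, adjusted p = 0.0738), nor in the other table (permutation test, adjusted p = 0.139, and 0.109 at promoters). Shares of a library add up to a fixed total, so a rise on some chromosomes by itself lowers the others. Within chromosome 3, counts over 95.4 to 96 Mb stood 4.85-fold above the normal mean in mPTCL 1, and those over 94.9 to 96.5 Mb 4.72-fold in mPTCL 2 and 4.0-fold in mPTCL 5. The interval shared by these 3 libraries held peaks of 34 genes, among them Mcl1, an anti-apoptotic member of the BCL2 family, which was singled out after its values were seen. Its 17 peaks summed to 9.37, 9.12 and 8.72 log2 CPM in mPTCL 1, 2 and 5, and to 6.86 to 7.05 in the other lymphomas. Ctss, 1 of the myeloid markers above, lies in the same interval.

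**Figure D3:**
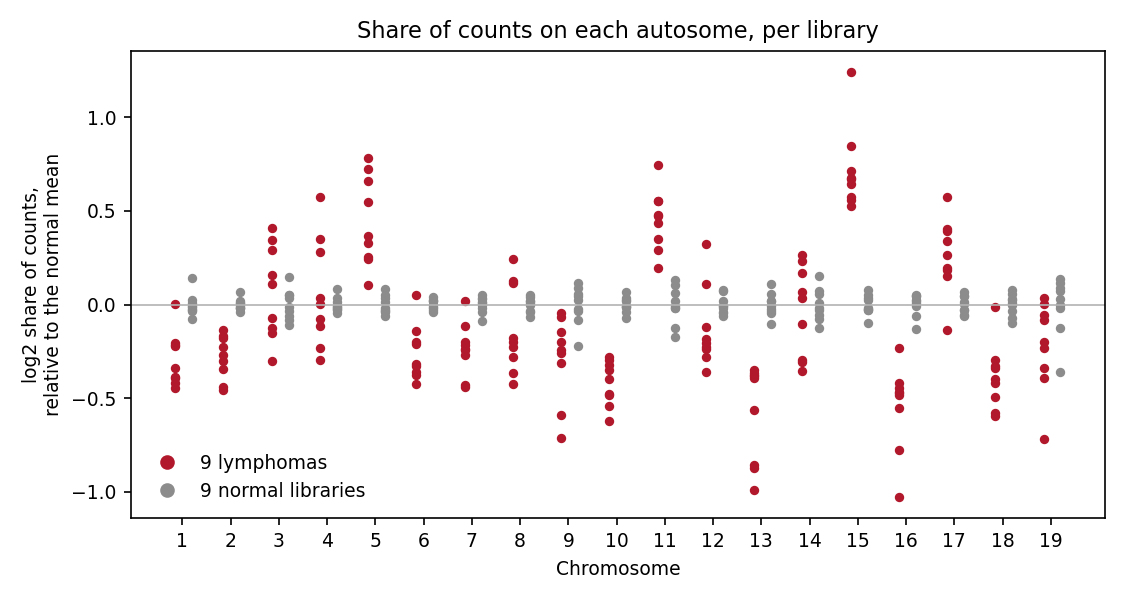
Log2 share of counts on each autosome relative to the mean of the 9 normal libraries, with a point per lymphoma (red) and per normal library (grey). The lymphoma mean was highest on chromosome 15 (0.72) and lowest on chromosome 13 (-0.57).

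**Figure D4:**
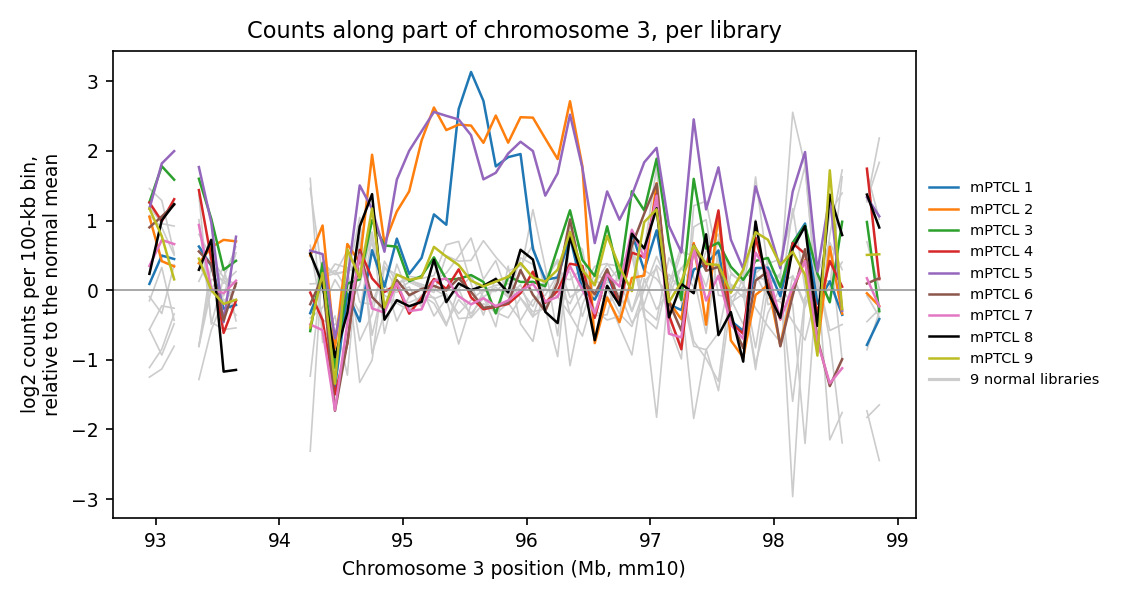
Log2 counts per 100-kb bin along part of chromosome 3 (mm10), relative to the normal mean, with a coloured line per lymphoma and grey lines for the 9 normal libraries. Only mPTCL 1, 2 and 5 stayed above 1.5 log2 units over 95.4 to 96 Mb. The median bin stood 4.85-fold above normal over that interval in mPTCL 1, and over 94.9 to 96.5 Mb 4.72-fold in mPTCL 2 and 4.0-fold in mPTCL 5.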

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

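A total of 160 groups of 9 lymphoma values (named genes, chromosome shares, the NK-over-T signature, similarity and total counts) were searched for a single library far from the other 8, and 14 held one; chance gives about 1 in 20. The 14 values fell on 7 libraries, and mPTCL 8, which had the lowest total count of the lymphomas, held 5 of them. All are log2 CPM per gene unless stated.

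In mPTCL 8, Ncr1 had 0 counts, for which the prior count gives -0.55, against 3.2 to 4.63 in the others, and Klrb1a, with 2 counts, lay at 1.77 against 3.62 to 4.72. In the same library Ccl3 lay at 7.18 against 4.63 to 5.22, Rora at 8.25 against 7.24 to 7.71, and the erythroid factor gene Tal1 at 3.84 against 4.87 to 5.27. In mPTCL 1, Slamf1 lay at 3.25 against 4.46 to 5.69, and Tox at 5.92 against 6.69 to 7.26. In mPTCL 5, Ccl5 lay at 6.43 against 7.15 to 7.74, and Zbtb32 at 5.54 against 4.09 to 4.59. Bach2 lay at 7.34 in mPTCL 3 against 7.76 to 8.20, Ifng at 5.54 in mPTCL 6 against 4.76 to 5.12, and Lat at 5.23 in mPTCL 2 against 4.02 to 4.61. Epor, the erythropoietin receptor gene, lay at 2.92 in mPTCL 9 against 3.77 to 4.52. The log2 share of chromosome 15 was 1.24 in mPTCL 2 against 0.52 to 0.85 in the others.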

How the results depend on the processing

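Of the alternatives, TMM within each chromosome, promoter peaks only, leaving out the 3 NK libraries and the 9 normal libraries alone were chosen after seeing the data. So was leaving out chromosomes 5, 11 and 15 for the location of peaks. The same holds for the other table for lists, named genes, the signature and similarity, and for cyclic-loess values for lists and named genes. The signature and similarity were not run on cyclic-loess values. Among named genes and gene lists, 8102 values under an alternative counted as unchanged, 456 lost a call and 220 gained one. A further 16 changed sign where either setting made a call. Values not called under either setting counted as unchanged whatever their sign, as did those without an adjusted p. Among the totals and summary values, 167 counted as unchanged and 64 as moved. The limit was 1.5 times for totals, 1 SD for similarity and a tolerance from the lymphoma subsets for the spread. The signature and the location of peaks were judged by direction and side of the threshold. The planned gene value from the peak nearest the TSS was not run, because the gene table used here gives no strand.

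Calls of mPTCL against NKT numbered 7567 on cyclic-loess values, 12052 at a mean count of at least 20 and 7008 in the other table, and 14458 to 27060 with 1 library left out. Against T they numbered 18306 with DESeq2, 7649 on cyclic-loess values, 4797 in the other table and 18396 with voom, and 6048 to 12670 with 1 library left out. Against NK they numbered 11269 on cyclic-loess values and 1832 with voom, and 3394 to 6964 with 1 library left out. NK against NKT gave 3775 in a fit on the 2 groups, 6473 on cyclic-loess values, 2906 at a mean count of at least 20, 2394 in the other table, and 4622 to 9560 with 1 library left out. NK against T gave 1843 on the 2 groups, 6126 on cyclic-loess values, 1870 at a mean count of at least 20, 1241 in the other table, 1100 with voom, and 1172 to 4097 with 1 library left out. NKT against T gave 5573 with DESeq2, 9960 on the 2 groups, 1510 on cyclic-loess values, 1905 at a mean count of at least 20, 1992 in the other table, 10898 with voom, and 1294 to 1831 with 1 library left out. The other table and the count minimum test fewer peaks; the cause of the other shifts was not tested.

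Replicate numbers showed no sign of pairing the normal libraries. Same-numbered libraries had a median correlation of deviations of 0.0109 (-0.0369 to 0.0465, 9 pairs) and others 0.00123 (18 pairs). With groups this small and the NK libraries this shallow, that cannot exclude a shared animal or day. With the replicate block over the 9 normal libraries, NK against NKT gave 4828 calls, against 6692 without the block on those libraries, and NKT against T gave 3943 against 5835. NK against T gave 2478 with the block and 3902 without it.

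Of the 16 lists, 7 were called against NKT, but 0 with an estimated correlation (5 at an unadjusted p below 0.05), 3 on cyclic-loess values and 2 of 15 in the other table, where the hepatocyte markers were not tested. Against T, 3 were called, but 0 with an estimated correlation (6 at an unadjusted p below 0.05), 6 with TMM within each chromosome, 1 of 15 in the other table, 8 without the 3 NK libraries, and 3 to 7 with 1 library left out. Similarity in the other table was 0.719 for NKT, 0.661 for T and 0.660 for NK, and the NK spread was 0.81 at a mean count of at least 20. The signature difference ranged from 1.08 to 1.2 with 1 library left out.

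With TMM within each chromosome, Grap2 changed sign to -0.45 against NKT and -0.17 against T, Itgb7, mPTCL vs NKT, to -0.0098 and against T to -0.17, and Nr4a1 to -0.45 and -0.092. In the other table, Ebf1 changed to -0.011, Klrd1 to -0.36 and Klre1 to -0.042 against T. From promoter peaks, Irf4 changed to 0.039 and Zeb2 to 1.02 against NKT, Klrd1 to -0.13, Rasgrp1 to 0.24 and Tnfrsf10b to 0.85 against T, and Zfp683 to -0.10 against NK. On cyclic-loess values, Tek changed to -0.31 against NKT. The cause was not tested.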

Other observations

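Relative to 10000 random lists matched on mean level, the homing and residency genes of the lymphomas lay high against NKT cells although camera did not call them, with a median of 0.36 at percentile 99.8. The TCR genes lay at percentile 0 and the NKT-cell genes at 0.23, while NK receptor signalling lay at 99.96. The T-cell transcription factors, which camera had called lower, lay at percentile 39.9 (median -0.24, matched lists -0.20), so they did not stand out at their level. Against T cells, the NK and effector transcription factors lay at percentile 99.6 and the p53 targets at 0.16. These percentiles describe these libraries and carry no p-value.

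The tests on the choice of peaks, on sequencing depth and on a trend with signal level below were chosen after the result was seen, as was the reading of the marker lists described there. Of 100 splits of the libraries, the real one included, only 1 called as many peaks as the real split in each mPTCL comparison. The calls were 26096 against NKT (next 392), 12060 against T (next 464) and 5996 against NK (next 303). Random relabelling of these libraries thus gave far fewer calls. Such splits reuse the same libraries, so they cannot exclude differences between animals or batches. For the normal groups, the 10 splits are too few for a share under 0.05. The real split, 1 of 10 in each, called 10496, 2936 and 3202 peaks for NK against NKT, NK against T and NKT against T, and the highest other split called 0, 1 and 0.

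Shares of counts moved across most of several chromosomes. On chromosomes 5, 11 and 15, all 70 of the 5-Mb bins (100%) lay above the median of all bins, and on the lowered chromosomes 2, 10, 13 and 16, 88 of 104 (84.6%) lay below it. The rise was present in promoter peaks of the other table (0.68 for chromosome 15), so it was not confined to the main table's peaks. Chromosome 15 held 7.75% of the peaks in the main table and 4.65% in the other. The other table shares 14905 intervals with the main one and its rule is unknown, so it cannot exclude an effect of the choice of peaks. The rise was absent in the shallow NK libraries (0.0057), which argues against depth. Gains of whole chromosomes are a candidate explanation of the rise. For the counts of a chromosome, 3 copies in place of 2 would give 0.585. The shares rose by a mean of 0.72 on chromosome 15 and 0.45 on chromosomes 5 and 11. A share also depends on the counts of all other chromosomes, so these values cannot be read as copy numbers. No DNA copy number was measured, and a change in the activity of whole chromosomes stays open. If copies were gained, genes there, such as Trp53 and Myc, would rise without any change per copy.

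Counts over 95.4 to 96 Mb of chromosome 3 were raised in mPTCL 1, 2 and 5. At least 99.1% of the peaks there lay above the normal mean in these libraries, at promoters and elsewhere, but the interval was drawn from bins already raised in them, so this share does not test a focal copy gain. Such a gain stays open, as does a change in the activity of the region. The main table has 628 peaks in the 1-Mb bin at 95 Mb (median bin 20), so this signal may have entered the choice of peaks, whose rule is unknown. Promoter peaks of the other table were also raised there, by at least 2.05 log2 units in these libraries. A minimum of 50 peaks per bin was chosen after a scan at 10 peaks had put 3 to 12 bins per lymphoma, 5 to 8 per NK and 0 per T or NKT library above 1.5 log2 units, and after a running median had proved noisy. At 50 peaks, the bin at 96 Mb also passed in mPTCL 5 (1.58), where it overlaps the same block, and the only bin elsewhere was 1 below in mPTCL 6 (chromosome 10, -1.61).

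Several markers of other cell types were higher in the lymphomas than in NKT cells (B-cell markers averaged 4.12 against 2.65 log2 CPM, hepatocyte markers 4.21 against 2.70), and cells carried through the sort, whose markers the labels do not name, are a candidate source. The median lay at percentile 91.7 of matched lists for B-cell, 96.3 for myeloid, 93.6 for hepatocyte, 98.0 for endothelial and 57.7 for erythroid markers, so the endothelial list alone passed the upper bound set in advance, and at 99.9 for all 36 genes pooled. A median within the matched range was set in advance as evidence against such cells, but for lists of 5 to 10 genes that range is wider than the medians, so after the values were seen it was read as undecided. Matched lists themselves had a median of 0.64 against 1.54 pooled, and on cyclic-loess values the pooled median was 0.59, so neither weak sites nor a trend with level can be told apart from such cells. NK cells, sorted from spleen, showed a pooled 1.27 over NKT cells (matched 0.26), so the rise is not particular to the lymphomas.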
